A study of Homo sapiens with 16 samples.

How the data were processed

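RNA was measured in human monocytes that had been isolated from blood of healthy donors with Ficoll and attached to plastic. The cultures received saline or diesel exhaust particles (DEP, the soot of diesel engines). Total RNA was extracted with Trizol, labelled with biotin through a 3' in vitro transcription kit and hybridized to Affymetrix arrays. The series holds 16 arrays, 8 with saline and 8 with DEP. The dose, the exposure time, the array batches and the genome build are not given in the sources used here, so no gene positions are printed.

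Per the labels, the deposited values are log2 values that the authors made with GCRMA, which corrects background from probe sequence, normalizes across arrays and summarises each probe set. Its version is not given in the sources used here. The table holds 54675 probe sets, and all arrays share a lowest value of 2.30. A value within 0.1 of it is called at the floor. No raw intensities were used here. Arrays carry no count of molecules, so the number of arrays limits the precision.

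Probe sets were named from the array annotation. Of these, 41097 carried 1 gene symbol, 1801 carried several, 11777 were not named here and 62 were controls. The gene identifier and the symbol of 41043 of the named probe sets were found in the RefSeq gene table. A gene was represented by its probe set with the highest mean over the 16 arrays, which gave 19775 genes. The 9434 genes with at least 4 arrays above 4 on the log2 scale were tested, and 6461 of them had more than 1 probe set. Probe sets with several symbols, among them those of HSPA1A and HSPA1B, are not named. Genes of a list without a probe set of 1 symbol are not analysed here.

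Treatment was tested over all genes with limma 3.58.1 in R 4.3.3 (linear model on treatment, moderated variance, two-sided). Values of p were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. "Called", "rose" and "fell" refer to that threshold, and a difference is always DEP minus saline. Errors of a difference are standard errors (SE) from the linear model, and errors of a group mean are standard deviations (SD). Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

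The sample titles hold a code that 1 saline and 1 DEP array share. The labels do not say what the code stands for, so the main comparison does not use it. Arrays that share a code are called pair 1 to pair 8 here, and the number of pairs in which a gene moved the same way is given as a description. The labels also do not say that each array comes from a separate donor or culture, so the p-values measure only the spread between arrays.

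Fixed lists of genes, 29 in number, were compared with all other tested genes by limma's camera test at a preset inter-gene correlation of 0.01, with adjustment over the 27 lists that had at least 3 tested genes. The same test with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were run beside it. For each list the counts of called members are given over all genes and adjusted over the list alone. A list's relative change is the median log2 difference of its members minus that of all tested genes. A called list is given the direction of its test, and any other list the sign of its relative change, a convention chosen after the results were seen. RNA quality and array quality were compared between the groups by exact permutation tests on 1 value per array.

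The tests, the filter, the lists and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes that moved the same way in at least 7 of the 8 pairs. It added members of the fixed lists, first those called without or with the title code in the model, by size of change, and for called lists with under 2 such genes the 2 largest changes. It also added fixed central genes of the AhR, NRF2, Notch and allergic lists. Genes named outside this rule are said to have been chosen after their values were seen, and so were the members of lists that are named only from the fit with the technical set as a block.

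The alternatives fixed in advance were the title code as a block or as a random effect, no filter and a stricter filter (at least 8 arrays above 6), quantile normalization, centring on all probe sets, the mean of all probe sets of a gene, array weights, a trended robust variance, an unmoderated two-sample test, other thresholds, and leaving out each pair. Chosen after seeing the data were 3 technical sets of arrays as a block, leaving out the DEP array of pair 4, both together, leaving out the DEP arrays of pairs 4, 5 and 6, centring on the tested genes, and leaving out each single array. The technical sets separate the arrays at the largest gaps in the 18S ribosomal RNA control, without regard to treatment, and the DEP array of pair 4 was placed with the saline array of its code.

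The main comparison, which has no block, was tested on simulated data with 8 arrays per group and 9434 genes. It recovered 8% of genes changed by 1 on the log2 scale, 42% of those changed by 2, 84% of those changed by 4 and 98% of those changed by 6, with 50 genes at each size. Of 118 calls, 2 were false, and 2 of 200 lists without a shift had a camera p under 0.05. The simulated genes varied independently of each other, so the figure for lists does not hold for correlated genes. When the real arrays were split at random, 20 of 100 splits, the real one included, called at least 8 lists. Most of these splits held part of the real grouping, so the share is not a rate of false calls.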

Results

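The data are 16 expression arrays of cultured human blood monocytes, 8 after saline and 8 after diesel exhaust particles (DEP). The series asks whether traffic-related particles raise allergic responses through the Notch pathway, in which receptors on a cell's surface release a transcription activator after contact with a ligand. The single comparison the design gives is DEP against saline.

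The arrays fell into 3 sets by their control values, each holding saline and DEP arrays alike. They are called technical sets here, but the labels give no batch. Whether processing or the cultures set them apart was not tested. Saline arrays also differed between the sets in HES1, which was at 9.99 and 8.42 in pairs 5 and 6 and at 2.30 to 4.74 in the other pairs. In set 1 (pairs 1 to 4, 8 arrays) the 18S ribosomal RNA control lay between 12.1 and 13.4 on 7 arrays, and the ACTB 3' control between 14.98 and 16.04 on the log2 scale. In set 2 (pairs 5 and 6, 4 arrays) these ran from 15.0 to 15.6 and from 14.5 to 15.2. In set 3 (pairs 7 and 8, 4 arrays) they ran from 9.45 to 10.2 and from 6.97 to 8.83. The DEP array of pair 4 stood apart from all others. Its cre control, a transcript added to the hybridization mix, was at 6.01 against 16.08 to 16.97 on the other 15 arrays. The SD over all its probe sets was 1.88 against 2.44 to 2.95, and its highest correlation with any other array was 0.787 against 0.926 to 0.989. The median of the tested genes was 5.23 on that array, and 6.20 and 5.94 on the DEP arrays of pairs 5 and 6. The 5' minus 3' log2 difference of GAPDH, a sign of RNA degradation, differed between DEP and saline by 0.022 (exact permutation p = 0.986, n = 8 each), and that of ACTB by -1.24 (exact permutation p = 0.393) or by -0.219 without the DEP array of pair 4.

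**Figure D1:**
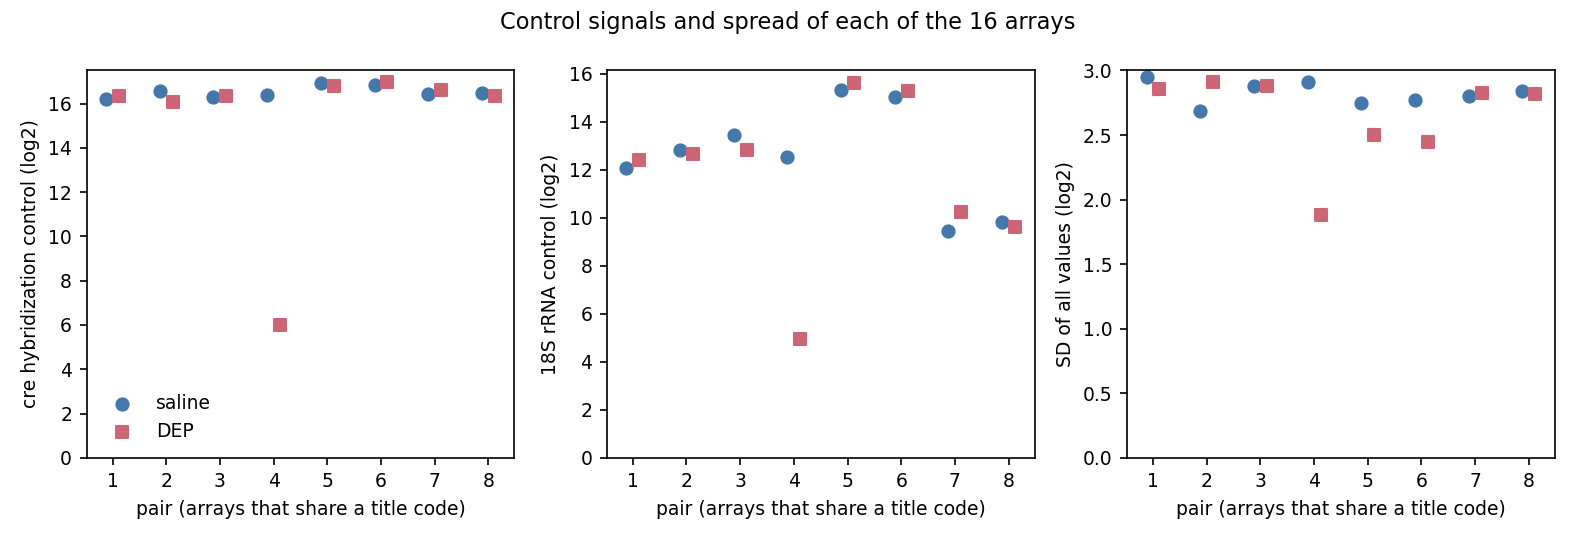
Control values of the 16 arrays by pair, with saline as circles and DEP as squares: the cre hybridization control, the 18S ribosomal RNA control and the SD over all probe sets, all on the log2 scale. The cre control of the DEP array of pair 4 is at 6.01 against 16.08 to 16.97 elsewhere, and the 18S control separates 3 sets of arrays.

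After DEP, monocytes held more RNA of several chaperones, of the glutathione synthesis gene GCLM and of the Notch target genes HES1, HES4 and NRARP. They held less RNA of the chemokine receptor CCR2 and of the interferon-induced genes CXCL10, IFIT2 and IFIT3. The largest rise was in DNAJA4, an HSP40-type co-chaperone, by 7.14 ± 0.56 (SE) on the log2 scale, or 141-fold. Its level went from 5.14 ± 1.35 (SD, n = 8) with saline to 12.28 ± 0.88 (SD, n = 8) with DEP, higher in 8 of 8 pairs (limma, adjusted p = 1.23e-06). The largest fall was in CCR2, the receptor through which monocytes follow the chemokine CCL2, by 7.06 ± 0.48 (SE), or 133-fold, from 12.23 ± 0.48 (SD) to 5.17 ± 1.26 (SD), in 8 of 8 pairs (adjusted p = 2.94e-07). Within sets 1, 2 and 3 the DNAJA4 difference was 8.24, 7.67 and 5.13, and the CCR2 difference was -7.33, -8.13 and -5.75, with set 1 taken here and in all later within-set values without the DEP array of pair 4.

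Of 9434 tested genes, 86 were called higher with DEP and 241 lower, so that 26.3% of the calls were higher. At an unadjusted p under 0.05 the counts were 293 and 1854. Of the called genes, 84 of those higher and 240 of those lower moved the same way in at least 7 of 8 pairs. Among all 9434 tested genes, all 8 DEP values lay on 1 side of all 8 saline values in 114, against a share of 0.0155% that chance alone gives. The deposited values place most genes lower on DEP arrays: the median log2 difference of all tested genes was -0.594, and -0.367 without the DEP array of pair 4, -0.220 after quantile normalization and 0.152 after centring on the tested genes. The split of the calls moved with this shift, since 54.5% were higher after quantile normalization and 79.1% after centring on the tested genes. Without the DEP arrays of pairs 4, 5 and 6 the median difference was -0.078, and 338 genes were higher and 173 lower (66.1% of the calls higher). Changes of gene lists, also within the sets, are therefore given relative to the median gene, whose own difference was -0.17 in set 1 (without the DEP array of pair 4), -0.86 in set 2 and -0.07 in set 3. With the technical set as a block and without the DEP array of pair 4 (the set-block fit), 529 genes were higher and 1705 lower, among them all 86 and all 241. The median difference of all tested genes in the set-block fit was -0.35, and the differences of single genes are not set against it. Counts of list members called in this fit are to be read against the 529 higher and 1705 lower of 9434 genes. A few members called lower there say little about a list by themselves. Members of lists that are named below only from the set-block fit were chosen after their values were seen.

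The counts also moved when 1 array was left out. The number of genes higher with DEP went from 86 to 53 without the saline array of pair 1, to 45 without the DEP array of pair 1 or of pair 2, to 51 and 47 without the saline arrays of pairs 3 and 4, and to 186 without the DEP array of pair 4. The number of genes lower with DEP went from 241 to 105, 364, 131, 98, 136 and 152 without the saline arrays of pairs 1, 2, 3, 4, 7 and 8, and to 122, 143, 113 and 134 without the DEP arrays of pairs 1, 2, 5 and 6. Within set 1 without the DEP array of pair 4, 415 genes were higher and 390 lower. In set 2 the counts were 156 and 1631, and in set 3 they were 144 and 93.

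Of the 12 largest rises, 7 were in chaperones or their partners. Beside DNAJA4, these were HSPA6 (5.72 ± 1.06, SE), an HSP70 made almost only under stress, HSPA1L (5.27 ± 1.28) and HSPA2 (4.49 ± 0.71), both of the HSP70 family, DNAJB4 (5.07 ± 0.92), HSPB1 (4.79 ± 1.18), a small heat shock protein, and BAG3 (4.63 ± 0.98), which hands HSP70 clients to autophagy. Their adjusted p (limma) ran from 1.23e-06 to 0.0332, and each was higher in 7 or 8 of 8 pairs. In sets 1, 2 and 3 the HSPA6 difference was 7.02, 7.99 and 5.33, and the BAG3 difference was 6.70, 4.32 and 5.30, while HSPA1L differed by 5.96 and 9.36 in sets 1 and 2 and by 0.000241 in set 3. HSPA1L lay at the same lowest value of 2.79 on 7 of 8 saline arrays and on both DEP arrays of set 3, so neither the size of its rise nor its place among the 12 is measured on both sides. The DEP array of pair 4 was the lowest of its group for HSPA6, DNAJB4 and BAG3. HSPA1L was no longer called without any 1 of the saline arrays of pairs 1, 3, 4, 7 and 8 or the DEP arrays of pairs 1, 2, 5 and 6 (adjusted p 0.0537 to 0.0630). HSPB1 was no longer called without any 1 of the saline arrays of pairs 1, 3, 4, 7 and 8 or the DEP arrays of pairs 1, 2, 3, 5 and 6 (0.0526 to 0.0663).

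The fixed list of heat shock genes lay far above the other genes. Of its 8 tested members, 4 rose and none fell. These were HSPB1, BAG3, HSPE1 (4.44 ± 0.94, SE, adjusted p = 0.0179), the mitochondrial co-chaperonin, and HSPH1 (4.16 ± 0.86, adjusted p = 0.0166), an exchange factor of HSP70. Adjusted over the list alone, 6 rose. DNAJB1, the HSP40 partner of HSP70, differed by 4.18 ± 1.16 (adjusted p = 0.0542), and was called without the DEP array of pair 4 (adjusted p = 1.02e-06). HSPA4L, of the HSP110 family, differed by 2.39 ± 0.69 (adjusted p = 0.0609), a lower bound since 5 of 8 saline arrays were at the floor, and was called without the DEP arrays of pair 6 (0.0434) or pair 7 (0.0331). The list's relative change was 4.76 (camera, adjusted p = 4.14e-13, and adjusted p = 0.0461 with an estimated correlation). With fry the adjusted p was 0.103, and 3.96e-08 in the set-block fit. The relative change was 5.72, 4.30 and 4.63 in sets 1, 2 and 3. All 8 were higher in the set-block fit.

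**Figure D2:**
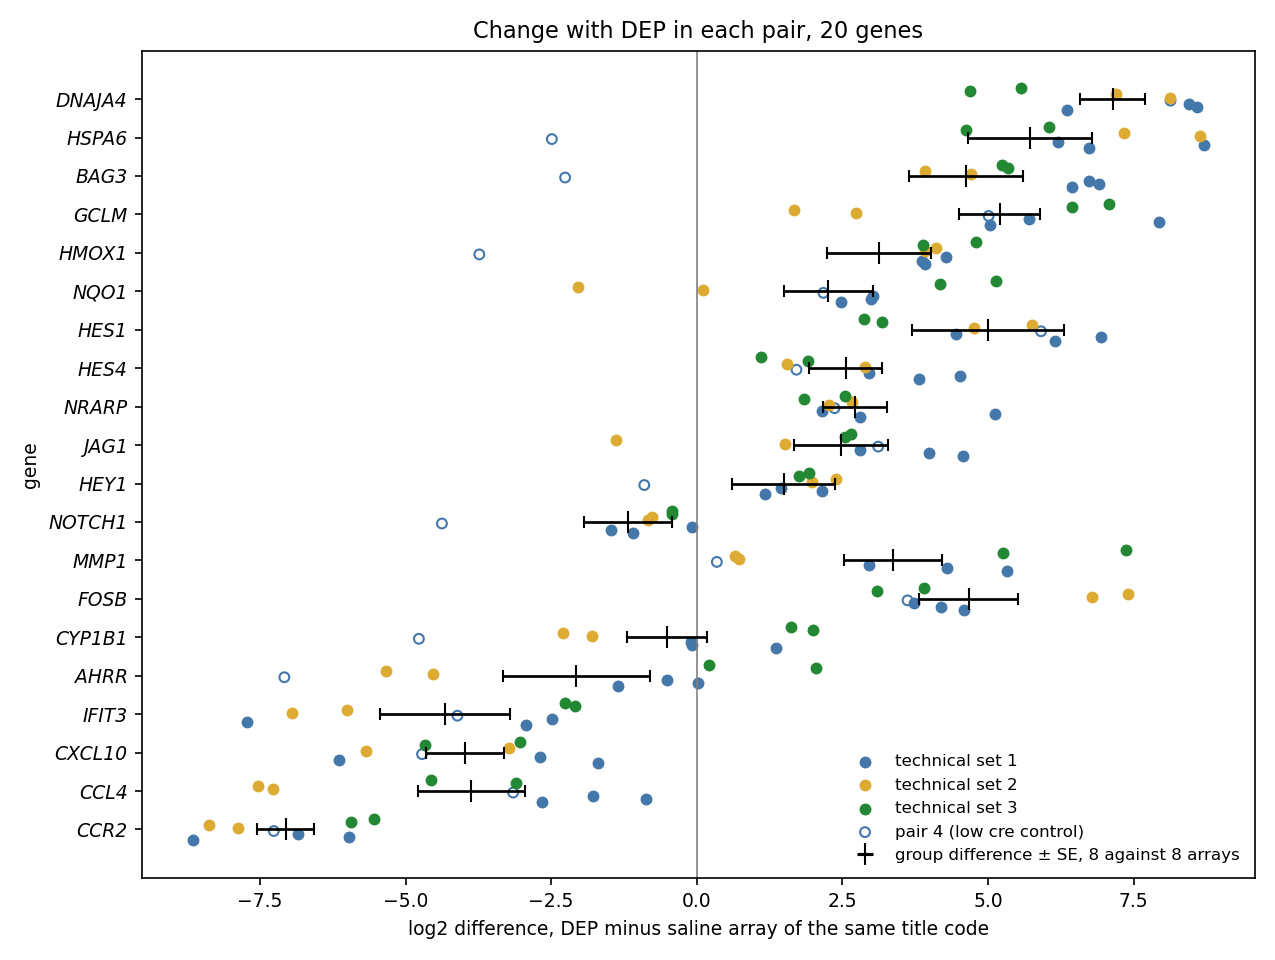
Log2 difference DEP minus saline of 20 genes, with 1 point per pair coloured by technical set (hollow for pair 4) and the group difference with its SE in black. DNAJA4 is higher in 8 of 8 pairs, with a difference of 7.14, and CCR2 lower in 8 of 8, with a difference of -7.06.

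Genes of the NRF2 pathway, the cell's programme against oxidants and electrophiles, were called higher with DEP as a list, with a relative change of 1.26 (camera, adjusted p = 6.80e-08, and adjusted p = 0.446 with an estimated correlation). GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis, rose by 5.20 ± 0.70 (SE), or 36.9-fold, in 8 of 8 pairs (limma, adjusted p = 0.000718). OSGIN1, a gene induced by oxidative stress, rose by 3.78 ± 0.76 in 7 of 8 pairs (adjusted p = 0.0148). HMOX1, which encodes heme oxygenase 1, differed by 3.13 ± 0.90 (adjusted p = 0.0596, 7 of 8 pairs), and without the DEP array of pair 4 by 4.08 (adjusted p = 3.18e-07, against a range of 3.27e-09 to 0.155 over the alternatives for HMOX1). NQO1, a quinone reductase that AhR also controls, differed by 2.26 ± 0.76 (adjusted p = 0.0977, 7 of 8 pairs). Of 18 tested NRF2 target genes, 2 rose and none fell, and 4 rose adjusted over the list alone. There were 11 higher in the set-block fit.

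Within the technical sets, the relative change of the NRF2 target genes was 1.91 in set 1, 0.62 in set 2 and 2.20 in set 3, and the interaction of set 2 with the others was called for the list (camera, adjusted p = 0.00137, and adjusted p = 0.859 with an estimated correlation). GCLM differed by 6.04, 2.20 and 6.76 in sets 1, 2 and 3, OSGIN1 by 4.94, 0.95 and 6.14, and NQO1 by 2.98, -0.97 and 4.66. HMOX1 differed by 4.05, 4.02 and 4.33. An interaction test of set 2 against the other sets gave -4.10 for GCLM (adjusted p = 0.00537), -4.43 for OSGIN1 (adjusted p = 0.00758) and -4.57 for NQO1 (adjusted p = 0.00170), and -0.14 for HMOX1 (adjusted p = 0.850).

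Of the Notch target genes, 3 rose with DEP. HES1, a transcriptional repressor and the best-known Notch target, rose by 5.0025 ± 1.31 (SE), or 32.1-fold, from 4.94 ± 2.75 (SD, n = 8) to 9.94 ± 2.997 (SD, n = 8), in 8 of 8 pairs (limma, adjusted p = 0.0432). HES4, a related repressor, rose by 2.56 ± 0.63 (adjusted p = 0.0341), and NRARP, a feedback inhibitor of Notch signalling, by 2.72 ± 0.55 (adjusted p = 0.0159), each in 8 of 8 pairs. HES4 passed the filter through DEP arrays only, since its saline values ran from 2.30 to 3.99, so the size of its rise is poorly measured. Of 11 listed Notch target genes, 5 were tested. HES2, HES5, HEY2, HEYL, DTX1 and CCND1 were too low, with 4.27 for HEY2 as their highest level on any array. Of the 5 tested, HES1, HES4 and NRARP rose and none fell, also adjusted over the list alone. The other 2 did not pass: HEY1, a repressor of the same family, differed by 1.49 ± 0.88 (adjusted p = 0.321, higher in 7 of 8 pairs), and MYC, a growth regulator, by -0.69 ± 0.58 (adjusted p = 0.492, lower in 6 of 8 pairs, -0.27 without the DEP array of pair 4 and 0.051 after centring on the tested genes). The list's relative change was 3.15 (camera, adjusted p = 3.54e-06, and adjusted p = 0.0133 with an estimated correlation). In the set-block fit, 4 of the 5 were higher, HES1 by 5.06 ± 0.49 (adjusted p = 1.15e-05, against a range of 1.15e-05 to 0.137 over the alternatives for HES1), and the list's adjusted p with an estimated correlation was 0.0603.

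The 3 called genes were higher in each technical set, and the list's relative change was 3.61, 3.08 and 1.92 in sets 1, 2 and 3. HES1 differed by 6.14, 5.26 and 3.02 in sets 1, 2 and 3, HES4 by 3.79, 2.21 and 1.51, and NRARP by 3.44, 2.47 and 2.19. A second, dimmer HES1 probe set (mean 3.88 over all arrays) differed by 2.11 over all arrays. HEY1 differed by 1.94, 2.19 and 1.84, and MYC by -0.24, 0.77 and -1.37. In the fit without a block, the calls of HES1 and HES4 were close to the threshold. HES1 was no longer called without any 1 of the saline arrays of pairs 1, 2, 3, 4, 7 and 8 or the DEP arrays of pairs 1, 2, 5 and 6 (adjusted p 0.0593 to 0.0952). HES4 was no longer called without any 1 of the saline arrays of pairs 1, 3, 4, 6, 7 and 8 or the DEP arrays of pairs 1, 2, 3 and 5 (0.0527 to 0.0681).

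The receptors, ligands and machinery of the pathway were not called as a list, with a relative change of -0.21 (camera, adjusted p = 0.224, and -0.41 to -0.07 with 1 array left out) and members on both sides. JAG1, a Notch ligand, differed by 2.48 ± 0.80 (SE, adjusted p = 0.0866, 7 of 8 pairs), by 3.83 in set 1, 0.06 in set 2 and 2.60 in set 3, and was called only without the DEP array of pair 6 among the fits that left out 1 array (adjusted p = 0.0388, against a range of 4.97e-05 to 0.221 over the alternatives for JAG1). The receptors NOTCH1 and NOTCH2 differed by -1.19 ± 0.75 (adjusted p = 0.358, 8 of 8 pairs lower) and -0.38 ± 0.33 (adjusted p = 0.504), NOTCH1 by -0.61 without the DEP array of pair 4, and NOTCH2 by -0.21 without that of pair 6 and by 0.37 after centring on the tested genes. The ligand DLL1 differed by -0.04 ± 0.78 (adjusted p = 0.978), and by -0.43 to 0.32 with 1 array left out. LFNG and MFNG, glycosyltransferases that modify Notch receptors, differed by -2.89 ± 0.80 (adjusted p = 0.0530) and -1.77 ± 0.52 (adjusted p = 0.0616), each lower in 8 of 8 pairs. LFNG was called without the saline arrays of pair 5 (0.0478) or pair 6 (0.0427) or the DEP array of pair 7 (0.0331), and MFNG without the DEP arrays of pair 7 (0.0311) or pair 8 (0.0331). Over all arrays and without a block, none of 19 tested members of the list was called by limma or by the unmoderated test, with 1 higher and 6 lower at an unadjusted p under 0.05, and 1 rose and 3 fell adjusted over the list alone. In the set-block fit, 1 was higher, JAG1 (2.48 ± 0.53, adjusted p = 0.00424), and 5 were lower, LFNG (-2.86 ± 0.36), MFNG, APH1A, MAML1 and MAML2. That fit called 1705 of all 9434 tested genes lower. DLL4 was not tested, since its highest level was 2.94.

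Genes driven by the aryl hydrocarbon receptor (AhR), which binds polycyclic aromatic compounds, were called higher as a list, with a relative change of 0.95 (camera, adjusted p = 0.0130, and adjusted p = 0.446 with an estimated correlation). None of the 9 tested AhR target genes was called by limma, by the unmoderated test or adjusted over the list alone, with 1 higher and none lower at an unadjusted p under 0.05. Called higher in the set-block fit were 2, NQO1 and SLC7A5, an amino acid transporter (1.85 ± 0.43). The relative change was 1.47 in set 1, -0.10 in set 2 and 1.48 in set 3, and the interaction of set 2 was not called for the list (camera, adjusted p = 0.126, and adjusted p = 0.859 with an estimated correlation). CYP1B1, a cytochrome P450 induced through AhR, differed by -0.51 ± 0.68 (SE, adjusted p = 0.686), and by 0.34, -2.04 and 1.81 in sets 1, 2 and 3, by 0.03 without the DEP array of pair 4 and by 0.24 after centring on the tested genes. AHRR, the receptor's repressor, differed by -2.06 ± 1.26 (adjusted p = 0.339), and by -0.60, -4.93 and 1.13 in the sets. The interaction of set 2 was -2.92 for CYP1B1 (adjusted p = 0.0101) and -4.97 for AHRR (adjusted p = 0.00128). CYP1A1 was not tested, since its highest level on any array was 3.20.

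As a list, type I interferon genes were called lower with DEP, with a relative change of -1.49 (camera, adjusted p = 0.000389, and adjusted p = 0.709 with an estimated correlation). CXCL10, a chemokine induced by interferon, fell by 3.98 ± 0.67 (SE) in 8 of 8 pairs (limma, adjusted p = 0.00615), and IFIT2, which binds foreign RNA, fell by 3.94 ± 0.84 in 8 of 8 pairs (adjusted p = 0.0190). IFIT3, of the same family, fell by 4.32 ± 1.12 in 8 of 8 pairs (adjusted p = 0.0411). Of 20 tested members of the list, these 3 fell and none rose, and 7 fell adjusted over the list alone. IFIT1 differed by -3.81 ± 1.05 (adjusted p = 0.0531), and the antiviral genes MX1 and OAS2 by -3.23 ± 0.94 (0.0612) and -3.03 ± 0.90 (0.0649), each lower in 8 of 8 pairs. There were 10 lower in the set-block fit.

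The relative change of the type I interferon genes was -3.04 in set 1, -1.29 in set 2 and -0.08 in set 3. Within set 1 the members' median difference was -1.61, -5.32 and -1.30 in pairs 1, 2 and 3. The list was called in 7 of 8 fits that left out 1 pair, and its call ended without pair 2. The interaction of set 2 with the others was not called for this list (camera, adjusted p = 0.147, and adjusted p = 0.859 with an estimated correlation). CXCL10 differed by -3.80, -4.46 and -3.85 in sets 1, 2 and 3, IFIT2 by -3.79, -5.13 and -1.81, and IFIT3 by -4.62, -6.47 and -2.17. IFIT3 was no longer called without any 1 of the saline arrays of pairs 1 to 6 or the DEP arrays of pairs 1, 2, 5, 6, 7 and 8 (adjusted p 0.0514 to 0.0934). In the other direction, IFIT1 was called without the DEP arrays of pair 3 (0.0279) or pair 4 (0.0425) or the saline arrays of pair 7 (0.0497) or pair 8 (0.0374), MX1 without the DEP array of pair 3 (0.0280) or the saline array of pair 8 (0.0417), and OAS2 without the DEP array of pair 3 (0.0402).

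Among chemokines and cytokines, CCL4, which attracts monocytes and T cells, fell by 3.87 ± 0.91 (SE) in 8 of 8 pairs (limma, adjusted p = 0.0284), with differences of -1.75 in set 1, -7.41 in set 2 and -3.83 in set 3. It was no longer called without the saline arrays of pairs 1 (0.0625), 3 (0.0544) or 4 (0.0585) or the DEP array of pair 5 (0.0517). CCL4 was the only member called of 16 tested inflammatory cytokines and chemokines, also adjusted over the list alone. Besides CCL4, lower, the set-block fit called 4 members higher: PTGS2, the inducible cyclooxygenase (3.19 ± 0.50), the chemokines CXCL2 (2.09 ± 0.57) and CXCL3 (2.18 ± 0.61), and IL6 (0.94 ± 0.30). PTGS2 was also called without the DEP array of pair 4 alone (adjusted p = 0.00992, against a range of 0.000111 to 0.274 over its alternatives). The list's relative change was 0.57 (camera, adjusted p = 0.101), ran from 0.26 to 0.92 with 1 array left out, and it was called higher without the saline arrays of pairs 1 (0.0391), 2 (0.0472) or 3 (0.0382) or the DEP arrays of pairs 5 (0.0438) or 6 (0.0453). Of 10 NF-kB feedback genes, none was called by limma or by the unmoderated test, with 4 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone (relative change -0.99, adjusted p = 0.224, and -0.63 without the DEP array of pair 6). Of these 10, the set-block fit called 3 lower: the NF-kB inhibitors TNFAIP3 (-1.33 ± 0.24) and NFKBIA (-0.99 ± 0.26), and ICAM1 (-2.41 ± 0.62). TNFAIP3 was also called without the DEP array of pair 4 alone (adjusted p = 0.0419, against a range of 0.00143 to 0.158 over its alternatives). Over all arrays ICAM1, an adhesion molecule, differed by -3.16 ± 1.06 (adjusted p = 0.0975).

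The allergic and IL-4-type response genes were not called as a list. They bear on the outcome that the series names. None of 14 tested members was called by limma, by the unmoderated test or adjusted over the list alone, and 3 were lower and none higher at an unadjusted p under 0.05. In the set-block fit, 3 were lower and none higher: IL4R (-1.18 ± 0.34, adjusted p = 0.0203), IL13RA1, a receptor chain for interleukins 4 and 13 (-1.58 ± 0.49, adjusted p = 0.0292), and TGM2, a transglutaminase (-1.28 ± 0.41, adjusted p = 0.0344). That fit called 1705 of all 9434 tested genes lower, so 3 of 14 is near the share over all genes. Over the alternatives the adjusted p ran from 0.0292 to 0.522 for IL13RA1 and from 0.0202 to 0.648 for TGM2, which were both chosen after their values were seen. The list's relative change was -0.04, while camera gave the direction as up (adjusted p = 0.735), and it ran from -0.39 to 0.46 with 1 array left out. The relative change was -0.39 in set 1, -0.24 in set 2 and 0.13 in set 3. IL4R, a chain of the interleukin-4 receptor, differed by -1.46 ± 0.63 (SE, adjusted p = 0.181, 8 of 8 pairs lower), and CCL22, a chemokine for T helper cells of the allergic type, by -1.17 ± 1.59 (adjusted p = 0.687, and -1.92 to -0.56 with 1 array left out). CCL17 was not tested, since its highest level was 2.57. Among 14 MHC class II and costimulation genes, none was called by limma, by the unmoderated test or adjusted over the list alone, with 2 lower at an unadjusted p under 0.05 (relative change -0.38, adjusted p = 0.239, and -0.18 without the DEP array of pair 4 and -0.61 without that of pair 5). Called lower in the set-block fit were 2, HLA-DMB, which loads peptides (-1.05 ± 0.31), and CIITA, the master activator of these genes (-1.46 ± 0.44). These 2 of 14 are no larger a share than that over all genes in that fit. With the fit without a block, simulated genes with a log2 change of 1 were recovered in 8% of cases, so changes of that size were mostly not detectable in that fit. The set-block fit was not simulated, and it called differences near 1, such as -1.05 for HLA-DMB.

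Among classical monocyte markers CCR2 was the only 1 of 11 called, with 3 lower adjusted over the list alone. The list's relative change was -0.99 (camera, adjusted p = 0.0523), and -0.16 without the DEP array of pair 4 (0.1199). It was called lower without the saline arrays of pairs 1 (0.0341) or 5 (0.0458) or the DEP arrays of pairs 5 (0.0346), 6 (0.0412), 7 (0.0287) or 8 (0.0367). The relative change was -0.35, -0.04 and 0.03 in sets 1, 2 and 3. In the set-block fit CCR2, CD14, the lipopolysaccharide co-receptor (-1.90 ± 0.42), and CX3CR1 (-3.14 ± 0.73) were called lower. CX3CR1, the fractalkine receptor, differed by -3.31 ± 1.09 (SE, adjusted p = 0.0925), and was called without the saline array of pair 5 (0.0489). Of 10 macrophage markers, none was called by limma or by the unmoderated test, with 2 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (relative change 0.24, adjusted p = 0.923, and -0.10 to 0.46 with 1 array left out). CSF1R, the receptor for the macrophage growth factor CSF1, differed by -3.03 ± 0.89 (adjusted p = 0.0637, 8 of 8 pairs lower). CSF1R (-2.23 ± 0.31) and MERTK, a receptor for dying cells (-1.91 ± 0.49), were called lower in the set-block fit. These 2 of 10 are near the share over all genes in that fit (1705 of 9434).

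The remaining largest changes fell outside the fixed lists. FOSB, an AP-1 transcription factor, rose by 4.67 ± 0.85 (SE, limma, adjusted p = 0.00928), and the long non-coding RNA LINC00304 by 4.66 ± 0.56 (adjusted p = 0.000312). The probe set annotated to BABAM2-AS1, an antisense RNA, rose by 6.69 ± 0.67 (adjusted p = 3.98e-05). Falls came in IL27RA, a chain of the interleukin-27 receptor (-3.78 ± 0.56, adjusted p = 0.00175), in ARHGAP22, a GTPase-activating protein (-3.53 ± 0.40, adjusted p = 0.000158), and in the ion channel gene CALHM2 (-3.59 ± 0.44, adjusted p = 0.000381). Others came in SNX20, a sorting nexin (-3.89 ± 0.84, adjusted p = 0.0199), in SASH3, an adaptor of lymphocyte signalling (-3.52 ± 0.62, adjusted p = 0.00848), in MRTFB, a partner of serum response factor (-3.41 ± 0.60, adjusted p = 0.00848), and in SERPINF1, a secreted serpin (-3.39 ± 0.62, adjusted p = 0.00915). Each of these 10 genes moved the same way in 8 of 8 pairs. In set 2 against the others, the interaction was called for 5 of them: 2.95 for FOSB (adjusted p = 0.0405), -3.84 for IL27RA (adjusted p = 0.000554), -1.98 for BABAM2-AS1 (adjusted p = 0.0484), -1.91 for ARHGAP22 (adjusted p = 0.0488) and -3.19 for MRTFB (adjusted p = 0.0369).

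Among matrix and protease genes, MMP1, an interstitial collagenase, rose by 3.36 ± 0.84 (SE, limma, adjusted p = 0.0354), or at least 10.3-fold, since 4 of 8 saline arrays were at the floor and the others at 2.76 or less, with 4.14, 0.69 and 6.31 in sets 1, 2 and 3. MMP10, a stromelysin, rose by 2.34 ± 0.61 (adjusted p = 0.0432), or at least 5.06-fold, since 8 of 8 saline arrays were at the floor, with 2.76, 0.26 and 3.57 in the sets. Both were higher in 8 of 8 pairs. These 2 of 13 rose and none fell, also adjusted over the list alone. The list was called higher (camera, adjusted p = 0.0443, and adjusted p = 0.709 with an estimated correlation), with a relative change of 0.25 (0.33, -0.08 and 0.22 in sets 1, 2 and 3, and -0.01 to 0.72 with 1 array left out) and a members' median difference of -0.34. The set-block fit called MMP1 and MMP10 higher and PLAU, the urokinase gene, lower (-1.01 ± 0.26). The list's call over all arrays ended without the DEP arrays of pairs 1 (0.141), 2 (0.0935), 3 (0.0719) or 4 (0.1199) or the saline arrays of pairs 6 (0.0603), 7 (0.213) or 8 (0.219). MMP1 was no longer called without any 1 of the saline arrays of pairs 1, 3, 4, 5, 6, 7 and 8 or the DEP arrays of pairs 1, 2 and 7 (0.0505 to 0.0703). MMP10 was no longer called without any 1 of the 8 saline arrays or the DEP arrays of pairs 1, 2, 4 and 8 (0.0505 to 0.0830).

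ER stress and amino acid response genes and cell cycle genes were called higher as lists at the preset correlation, each with adjusted p = 0.446 with an estimated correlation. Without the DEP array of pair 4 the ER stress and amino acid response genes were also called with an estimated correlation (adjusted p = 0.00828), while they were not in the set-block fit (adjusted p = 0.0530 with an estimated correlation), nor were the cell cycle genes in either (0.463 and 0.545). Over all arrays no member was called by limma or by the unmoderated test. At an unadjusted p under 0.05, 2 of 14 and 0 of 7 members were higher, and none was called adjusted over the list alone. The ER stress and amino acid response genes had a relative change of 1.53 (camera, adjusted p = 8.64e-05), and of 1.44, 1.75 and 0.47 in sets 1, 2 and 3. DDIT3 and ATF3, transcription factors of the stress response, differed by 1.53 ± 0.60 (SE, adjusted p = 0.145) and 1.72 ± 1.16 (adjusted p = 0.390), and both were called without the DEP array of pair 4 (0.0355 and 0.00603), where ATF3 differed by 2.88. In the set-block fit, 7 of the 14 were higher. The cell cycle genes had a relative change of 0.73 (adjusted p = 0.0332), and of 0.23, 1.05 and 0.72 in the sets and 1.17 without the saline array of pair 8, and were not called without the DEP arrays of pair 4 (0.0876) or pair 8 (0.112). Their members' own median difference was only 0.14. By pair it was 4.72e-05, 0, 0 and 0.0025 in pairs 3, 4, 5 and 6, and 0.20 to 0.46 in pairs 1, 2, 7 and 8. In set 2 the members' median was 0.19, against -0.86 for all tested genes. PCNA, the sliding clamp of DNA replication, and AURKA, a mitotic kinase, differed by 1.07 ± 0.69 (adjusted p = 0.368, and 0.62 without the saline array of pair 2) and 0.87 ± 0.62 (adjusted p = 0.420).

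Other lists were not called by camera. TFEB, the transcription factor that drives lysosome genes, fell by 3.06 ± 0.71 (SE, limma, adjusted p = 0.0269, 8 of 8 pairs) and was the only 1 of 10 lysosome genes called, also adjusted over the list alone (relative change 0.22, adjusted p = 0.799, and -0.20 to 0.42 with 1 array left out). Its call ended without the saline array of pair 1 (0.0509) or the DEP array of pair 5 (0.0545), and a second TFEB probe set that passed the filter differed by only -1.40. The set-block fit called TFEB lower and CTSL, a cathepsin, higher (1.68 ± 0.32). No p53 target gene of 8 was called by limma or the unmoderated test, with 1 higher at an unadjusted p under 0.05 and 1 adjusted over the list alone (relative change 0.54, adjusted p = 0.0682). PMAIP1, which promotes cell death, differed by 3.13 ± 0.96 (adjusted p = 0.0729). The set-block fit called 3 higher, PMAIP1 (3.66 ± 0.38), the DNA damage gene GADD45A (2.47 ± 0.27) and the cell cycle inhibitor CDKN1A (1.44 ± 0.34). Without the DEP array of pair 4, PMAIP1 (0.0196), GADD45A (0.0145), ADM (0.00182) and ANKRD37 (0.0146) of the hypoxia list, MYLIP (0.0268) of the lipid list, the p53 list (0.0162) and the list of 12 hypoxia and glycolysis genes (0.0337) were called higher, and the p53 list also without the DEP array of pair 5 (0.0346). The relative change of the hypoxia and glycolysis genes over all arrays was 0.16 (adjusted p = 0.194), and -0.07 to 0.44 with 1 array left out. Relative changes were 0.41 for 7 metallothionein and zinc response genes (adjusted p = 0.241), 0.60 for 8 cholesterol synthesis genes (adjusted p = 0.160) and 0.35 for 12 lipid efflux and storage genes (adjusted p = 0.192). With 1 array left out, the first ran from 0.015 to 0.95 and the last from 0.12 to 0.54. In these 3 lists no member was called by limma or by the unmoderated test, adjusted over the list alone or at an unadjusted p under 0.05. The same held for the hypoxia list, except that 1 member was higher and 1 lower at an unadjusted p under 0.05. The set-block fit gave other counts. It called the hypoxia genes ADM (2.64 ± 0.26), ANKRD37 (1.94 ± 0.26), NDRG1 (0.81 ± 0.22) and BNIP3 (2.14 ± 0.58) higher and PFKFB4 (-1.02 ± 0.34) lower. Of the lipid genes it called MYLIP (1.89 ± 0.40), PLIN2 (1.93 ± 0.47) and PDK4 (1.76 ± 0.49) higher and NR1H3 (-1.70 ± 0.46) lower, and of the cholesterol genes INSIG1 (1.01 ± 0.30) higher, which over all arrays differed by -0.21.

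**Figure D3:**
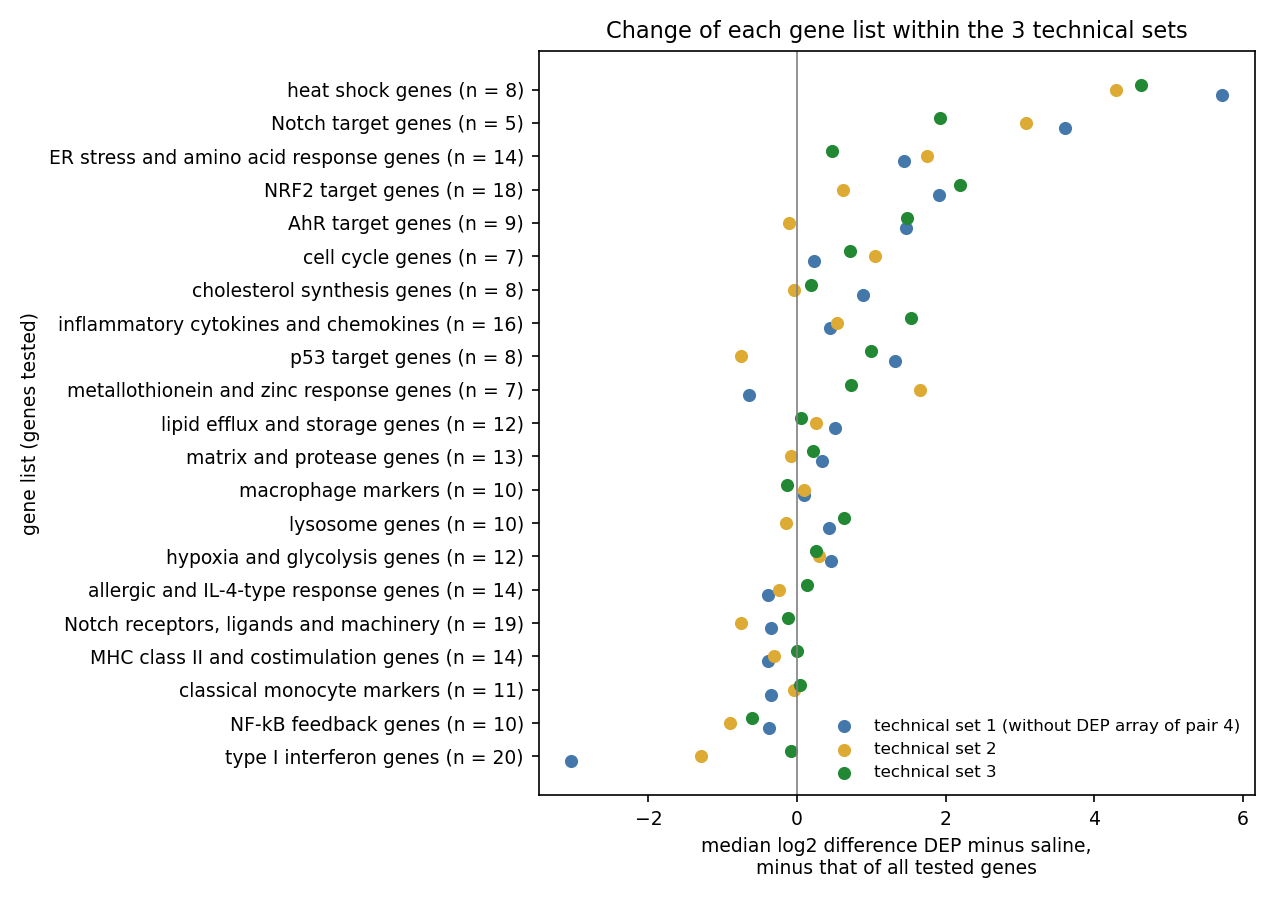
Median log2 difference DEP minus saline of the members of each gene list, minus that of all tested genes, in the 3 technical sets, with set 1 drawn without the DEP array of pair 4. The heat shock genes are at 5.72, 4.30 and 4.63 in sets 1, 2 and 3, and the AhR target genes at 1.47, -0.10 and 1.48.

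No marker of another cell type passed the test over all arrays. Of 32 tested markers of T, B and NK cells, platelets, neutrophils, erythroid cells, dendritic cells and fibroblasts, none was called by limma, by the unmoderated test or adjusted over the list alone, and 2 were lower and none higher at an unadjusted p under 0.05. Relative changes were -0.24 for T cell markers (camera, adjusted p = 0.923), 0.75 for B cell markers (0.648), 0.07 for NK cell markers (0.962), 0.69 for platelet markers (0.241) and -1.33 for dendritic cell markers (0.873). Neutrophil markers had a relative change of -0.16, while camera gave the direction as up (0.790). With 1 array left out, these values ran from -0.49 to 0.39 for T cell markers, 0.19 to 1.25 for B cell markers, -0.24 to 0.38 for NK cell markers, -2.01 to -0.83 for dendritic cell markers and -0.62 to 0.51 for neutrophil markers. LAMP3, of mature dendritic cells, differed by -3.50 ± 1.56 (SE, adjusted p = 0.195, 8 of 8 pairs lower). LAMP3 (-2.65 ± 0.41) and the neutrophil marker FCGR3B (-0.96 ± 0.29) were called lower in the set-block fit. Of the erythroid and fibroblast lists 1 gene each was tested, HBB with a difference of 0.49 and COL1A1 with 0.28. Of 8 list calls in all, those of heat shock genes and Notch target genes held with an estimated correlation over all arrays in the fit without a block, and that of Notch target genes did not in the set-block fit. Neither held with the title code as a block (camera with an estimated correlation, adjusted p = 0.184 for both).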

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

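The tests of the DEP array of pair 4, of the median shift and of the AhR genes in set 2 were chosen after the results were seen, and so were the technical sets on which several tests rest. Chance was weighed by 100 splits of the 16 arrays into 8 and 8, the real one included. For genes higher with DEP, 86 were called, the highest of the other splits gave 14, and 1 of 100 splits (the real one) reached 86, so chance is unlikely. For genes lower with DEP, 241 were called against at most 14 in another split, and again 1 of 100 splits, the real one, reached that count. For the lists, 8 were called, another split called 12, and 20 of 100 splits called at least 8, so chance cannot be excluded for the number of lists called. Most of these splits still held part of the real grouping, so their share does not measure chance alone. The split with 12 lists left 4 of 16 arrays in their own group and exchanged the rest, and a split counts the same as its mirror image. For the Notch target genes alone, the smallest camera p of the other splits was 7.14e-07, in a split that left 2 of 16 arrays in their own group, close to the mirror image of the real split. In the real split the camera p was 3.94e-07. Thus 1 of 100 splits, the real one, reached it, the smallest share that 100 splits can give. Chance is unlikely for this test at the preset correlation but is not excluded. The splits ignored the title codes and the technical sets, and with an estimated correlation the list's adjusted p (camera) was 0.0603 in the set-block fit. Of the 100 splits, 97 called no gene with limma.

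The DEP array of pair 4 lay far from the other 7 of its group in 18 of the 25 groups with such a value, among 160 groups of 8 that were examined. Chance flags about 1 in 20 groups. Its cre control of 6.01 lay 10.07 below the lowest other array, which a failed hybridization or scan of that array needs and which less or degraded RNA from that culture excludes as the whole cause, since cre is added to the hybridization mix. A failed hybridization therefore is a candidate explanation, but the loss was not uniform: the ACTB 3' control was at 15.10 and GCLM at 14.08, within the range of the other arrays of set 1 or of the DEP group. What set the lost probe sets apart stays open, as does damage to the RNA in addition (its ACTB 5' minus 3' difference was -10.61), and no biological explanation was tested.

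Most genes lay lower on the DEP arrays. The DEP array of pair 4 alone does not account for this, since the median difference of all tested genes was -0.367 without it and lay below 0 in 6 of the other 7 pairs. It was -0.46, 0.25 and -0.12 in pairs 1, 2 and 3, -0.74 and -0.94 in pairs 5 and 6, and -0.06 and -0.09 in pairs 7 and 8. Without the DEP arrays of pairs 4, 5 and 6 it was -0.078, so most of the shift lay in these arrays. Less RNA labelled from the DEP cultures cannot be told apart from other causes, because 7 pairs were too few: the change of the poly-A controls and the median gene change had a Pearson r of -0.574 (exact p = 0.176, BH 0.351, Spearman rho -0.429, exact p = 0.354), and r was -0.0666 without the 2 pairs farthest from the median. For the interferon genes, an array-wide shift of genes of their brightness was tested with 10000 lists matched on mean level. Their median of -1.91 (set as a block, without the DEP array of pair 4) lay at percentile 0 of these lists. The lists ran from -0.84 to -0.07 over their central 95%. Matched lists ignore the correlation between genes, and with an estimated correlation the interferon list's adjusted p in that fit was 0.578 (camera). The test therefore does not exclude such a shift. The effect of DEP on these genes stays open, and so does a difference in the interferon state of the cultures that held saline.

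The difference DEP minus saline of the AhR and NRF2 genes was lower in set 2 than in the other sets, with a median of -0.97 against 1.37 for the AhR target genes and of -0.24 against 1.91 for the NRF2 target genes, while all tested genes differed between the sets by a median of -0.82. Compressed DEP arrays in that set are a candidate explanation for the NRF2 genes that the test cannot single out. Members were unlike: the interaction was -4.10 for GCLM, -4.43 for OSGIN1 and -4.57 for NQO1, but -0.14 for HMOX1. The list's difference between sets of -1.94 lay at percentile 35.6 of lists matched on the rise in the other sets (-2.64 to -1.06). The difference is taken from that same rise, so spread alone also lowers matched lists. For the AhR genes the same explanation cannot be told apart from others: their difference of -2.92 lay at percentile 1.26 of such lists (-2.76 to -0.36), just past the edge, but matched lists ignore the correlation between genes, and with an estimated correlation the interaction had an adjusted p of 0.859. A biological difference between the cultures of the sets, or in the dose they received, was not tested.

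Further values of the DEP array of pair 4 on the log2 scale, each below the other 7 DEP arrays, were 6.458 for HSPA6, 5.789 for DNAJB4, 5.848 for BAG3, 7.166 for HSPH1, 6.54 for HSPE1 and 7.542 for HMOX1, and an SD of 1.883 over all its probe sets. Its mean level was 7.528 for NRF2 target genes, 6.684 for MHC class II and costimulation genes, 5.318 for ER stress and amino acid response genes and 5.819 for heat shock genes. It was 6.74 for lysosome genes, 5.901 for p53 target genes, 6.148 for hypoxia and glycolysis genes, 6.323 for classical monocyte markers and 5.627 for platelet markers. HSPA1L was at 4.501 on the saline array of pair 5, against 2.79 to 2.80 on the other saline arrays. On the same array HSPA2 was at 5.421, against 2.89 to 4.06. DNAJB4 was at 2.682 on the saline array of pair 2, against 6.03 to 7.64. CXCL10 was at 6.492 on the DEP array of pair 3, against 2.58 to 4.06 on the other DEP arrays, and the mean of the type I interferon genes on that array was 9.151, against 4.28 to 6.15. The GAPDH 5' minus 3' difference was -9.582 on the saline array of pair 7, against -3.82 to 0.00715 on the other saline arrays. On the other arrays of set 3 it was -4.59 (DEP, pair 7), -9.67 (DEP, pair 8) and -1.90 (saline, pair 8), so low values were not confined to 1 array of that set. The mean of the T cell markers was 8.486 on the saline array of pair 6, against 4.36 to 5.80.

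Of 2917 tested probe sets without a single gene name, which the report does not use and of which 863 carry several symbols, 19 were higher with DEP and 23 lower.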

How the results depend on the processing

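Chosen after seeing the data were the tests with technical sets, with single arrays or the DEP arrays of pairs 4, 5 and 6 left out, and with centring on the tested genes. The random effect and the unmoderated test were not run for lists. Over all alternatives, 4060 values of named genes kept their direction and side of the threshold, 364 passed it only there, 254 no longer passed it and 45 reversed; for lists and RNA quality these were 969, 49, 51 and 75. Of 37 called named genes, 25 were called with each single array left out and 13 under every alternative, DNAJA4 and CCR2 among them. Notch target genes were called under each of these alternatives, with adjusted p from 9.91e-09 to 0.0133, but not when an estimated correlation was combined with the set block without the DEP array of pair 4 (adjusted p = 0.0603) or with the title code as a block (next paragraph). Signal near the floor limits the genes not tested, and small changes were mostly missed in simulated data with the fit without a block. Except where fewer arrays or genes entered, the cause was not tested.

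With the title code as a block there were 167 genes higher with DEP and 798 genes lower with DEP, and as a random effect (consensus correlation 0.315) 213 and 1122. With this block and an estimated correlation, the adjusted p was 0.184 for heat shock genes and for Notch target genes. For single genes the adjusted p with this block (limma) was 0.00131 for HES1, 0.0101 for HES4, 0.00628 for NRARP and 0.0356 for HEY1. It was 0.0287 for JAG1, 0.00320 for LFNG and 0.0160 for MFNG. Not called were NOTCH1 (0.107), NOTCH2 (0.474) and DLL1 (0.957), and MYC was called under no alternative. The correlation within pairs ran from 0.042 to 0.765, above 0.1 in 6 of 8, and 9 of 16 arrays correlated best with their own code. Differences between the technical sets were not removed, and they also raise the correlation of arrays within a set. Sets 2 and 3 hold only 2 pairs each. These counts therefore do not show what the code stands for. The block is not used in the report, since the labels do not say what the code is.

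The number of genes higher with DEP (86) was 47 without a filter, 49 with the stricter filter, 174 after quantile normalization, 969 with array weights and 164 at an adjusted p under 0.10. It was 239 with the set block, 529 with the set block without the DEP array of pair 4, 186 without that array alone, 338 without the DEP arrays of pairs 4, 5 and 6, and 314 after centring on the tested genes. Leaving out pairs or arrays, it ran from 16 (without pair 1) to 328 (title code as a block, without pair 4). The number of genes lower with DEP (241) was 138 without a filter, 116 with the stricter filter, 145 after quantile normalization, 368 with the mean of all probe sets, 1873 with array weights and 671 at an adjusted p under 0.10. It was 1412 with the set block, 1705 with the set block without the DEP array of pair 4, 173 without the DEP arrays of pairs 4, 5 and 6, and 83 after centring. Leaving out pairs or arrays, it ran from 18 (without pair 1) to 1074 (title code as a block, without pair 2).

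Of the 7 lists called higher, 2 were called with an estimated correlation, 1 with fry and 4 after centring. Against 1 list called lower, 5 were without a filter, 3 after quantile normalization, 0 with an estimated correlation, 0 with fry and 3 after centring, and 0 (without pair 2) to 2 when pairs or arrays were left out.

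Relative changes of lists that turned, or passed the threshold only there, follow. Without a filter they were -0.66 for Notch receptors, ligands and machinery (adjusted p = 0.00746, range 0.00746 to 0.769), -0.12 for inflammatory cytokines and chemokines, -0.20 for metallothionein and zinc response genes, -0.21 for lipid efflux and storage genes, -0.011 for matrix and protease genes and -0.34 for lysosome genes. They were -0.057 for p53 target genes, -0.16 for hypoxia and glycolysis genes, -0.43 for macrophage markers, -0.24 for B cell markers, -0.16 for NK cell markers and 0.000157 for dendritic cell markers. With the stricter filter they were -0.21 for matrix and protease genes, -0.089 for hypoxia and glycolysis genes and -0.27 for platelet markers. After quantile normalization they were 0.0025 for allergic and IL-4-type response genes, -0.11 for matrix and protease genes and -0.22 for NK cell markers. NK cell markers were at -0.10 with the mean of all probe sets, -0.12 with array weights, -0.047 with the set block without the DEP array of pair 4 and -0.051 without that array. With array weights macrophage markers were at -0.35.

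For fry, the members' median difference, not set against the median gene, stood in place of the relative change. It was -0.020 for inflammatory cytokines and chemokines, -0.19 for metallothionein and zinc response genes, -0.24 for lipid efflux and storage genes, -0.34 for matrix and protease genes, -0.38 for lysosome genes, -0.059 for p53 target genes, -0.44 for hypoxia and glycolysis genes, -0.36 for macrophage markers and -0.53 for NK cell markers. Without the DEP arrays of pairs 4, 5 and 6, relative changes were -0.035 for lipid efflux and storage genes, -0.25 for macrophage markers and -0.26 for B cell markers. Without the DEP array of pair 4, neutrophil markers were at 0.14.

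Leaving out arrays or pairs, the range was -0.39 (without DEP array 5) to 0.46 (without saline array 5) for allergic and IL-4-type response genes, -0.014 (saline 8) to 0.72 (saline 4) for matrix and protease genes, -0.20 (saline 8) to 0.42 (DEP 4) for lysosome genes and -0.070 (DEP 7) to 0.44 (DEP 4) for hypoxia and glycolysis genes. It was -0.10 (DEP 5) to 0.46 (saline 5) for macrophage markers, -0.24 (saline 1) to 0.50 (pair 2) for NK cell markers, -0.62 (saline 3) to 0.51 (saline 8) for neutrophil markers and -0.49 (DEP 6) to 0.39 (saline 6) for T cell markers.

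DLL1 (-0.04) was at 0.25 after quantile normalization, 0.032 with the mean of all probe sets, 0.83 with array weights, 0.18 with the set block without the DEP array of pair 4, 0.52 without the DEP arrays of pairs 4, 5 and 6, and 0.70 after centring, and ran from -0.45 (without pair 2) to 0.32 (saline 3). CYP1B1 (-0.51) was at 0.26 with array weights, 0.093 with the set block without the DEP array of pair 4, 0.029 without that array, 0.53 without those of pairs 4, 5 and 6 and 0.24 after centring, and ran from -0.86 (without pair 7) to 0.10 (pair 4). MYC (-0.69) was at 0.051 after centring. INSIG1 (-0.21) was at 0.69 with the mean of all probe sets, 1.55 with array weights, 1.01 with the set block without the DEP array of pair 4, 0.96 without that array, 1.78 without those of pairs 4, 5 and 6 and 0.54 after centring, and ran from -0.51 (without pair 2) to 0.98 (pair 4). NDRG1 (0.17) ran from -0.23 (without DEP 8) to 0.88 (DEP 4). NOTCH2 (-0.38) was at 0.00068 without the DEP arrays of pairs 4, 5 and 6 and at 0.37 after centring. The GAPDH 5' minus 3' difference (0.022) was -0.12 without the DEP array of pair 4, and ran from -0.69 (without pair 7) to 1.14 (pair 8).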

Other observations

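The test of HES1 against JAG1 was chosen after the result was seen. Immediate-early genes, which cells switch on within a short time of a stimulus, held several large rises. NR4A2, an orphan nuclear receptor, rose by 4.17 ± 0.80 (SE, limma, adjusted p = 0.0135), the kinase gene SIK1 by 4.10 ± 0.99 (adjusted p = 0.0319), GEM, a small GTPase, by 4.12 ± 1.01 (adjusted p = 0.0332), CREM, a transcription factor of the cyclic AMP response, by 2.90 ± 0.66 (adjusted p = 0.0256), and NR4A1 by 1.76 ± 0.38 (adjusted p = 0.0199), GEM in 7 and the others in 8 of 8 pairs. KLF4 differed by 3.10 ± 0.87 (adjusted p = 0.0568). SIK1 was no longer called without any 1 of the saline arrays of pairs 1, 3, 4, 5 and 6 or the DEP arrays of pairs 1 and 2 (adjusted p 0.0535 to 0.0655). GEM was no longer called without any 1 of the saline arrays of pairs 3, 4, 7 and 8 or the DEP arrays of pairs 1, 2, 3 and 5 (0.0525 to 0.0671), and CREM without the DEP array of pair 1 (0.0528). KLF4 was called without the DEP array of pair 4 (0.0110) or the saline arrays of pairs 7 (0.0386) or 8 (0.0465). These genes were chosen after their values were seen, as was FOSB for this group.

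A shared rise of immediate-early genes was tested on the 16 tested genes of a list without FOSB, NR4A2, KLF4, SIK1 and GEM, which had suggested it. Of the 16, CREM and NR4A1 (named above) rose and none fell, with a median difference of 0.59. The camera p was 2.36e-06 at the preset correlation and 0.0635 with an estimated correlation, so that the test leaves the hypothesis open. With the technical set as a block and without the DEP array of pair 4, 7 rose and 1 fell, and the p with an estimated correlation was 0.0143.

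HES1 might follow its candidate upstream ligand JAG1. Over 7 pairs, without pair 4, the changes of HES1 and JAG1 had a Pearson r of 0.108 (exact p = 0.832, BH 0.832) and a Spearman rho of 0.357 (exact p = 0.444), with r = 0.547 without the 2 pairs farthest from the median. These are 2 relations computed in the same family, with that of the poly-A controls. In set 2 HES1 differed by 4.76 and 5.75 in pairs 5 and 6, where JAG1 differed by 1.51 and -1.39. With JAG1 lower in 1 pair only, the test leaves the hypothesis open. Protein was not measured.

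The change differed between set 2 and the other sets in 136 genes with a larger and 1553 with a smaller or more negative difference, with a median of -0.82 over all tested genes. HSPA1L (5.60, adjusted p = 0.0303) was among the first, and HSPB1 (-3.99, adjusted p = 0.00639), CCL4 (-4.89, adjusted p = 0.00170), MMP1 (-4.26, adjusted p = 0.0101), JAG1 (-3.32, adjusted p = 0.0172) and NOTCH2 (-2.03, adjusted p = 0.00534) were among the others. HES1 differed between the sets by 0.26 (adjusted p = 0.894). For lists, the interaction was called for the NRF2 target genes (camera, adjusted p = 0.00137, and adjusted p = 0.859 with an estimated correlation) and not for the AhR target genes (0.126, and 0.859 with an estimated correlation).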
